A study of Homo sapiens with 25 samples.

How the data were processed

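Chromatin from 4 human lung adenocarcinoma cell lines was immunoprecipitated and sequenced. The series labels describe formaldehyde-fixed, sonicated chromatin, paired 40 bp reads on a NextSeq 500 and the antibody of each library. There were 25 samples, 20 with a peak list (11 antibodies in NCI-H2087 and NKX2-1, H3K27ac and H3K4me1 in NCI-H358, NCI-H441 and HCC364) and 5 input libraries, for which no file was analysed here. Groups were taken from the sample titles, and each group of line and antibody is 1 library.

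Per the submitters' processing notes, Trimmomatic 0.36, Bowtie2 2.2.9, SAMtools 1.9, bedtools and MACS2 (2.1.1 and 2.2.7.1) were used and the build was hg38 (GRCh38). The notes used here give neither the role of each tool nor which MACS2 version made which list. The files deposited by the authors are peak lists called per library, in narrowPeak format, with no pooling visible in them. In the deposited lists column 7 is the fold of the summit over the local background, a linear ratio. Columns 8 and 9 of the deposited lists are the −log10 p and −log10 q of the peak caller. Column 10 is the distance of the summit from the peak start. The lowest −log10 q was just above 3 in every list (for example 3.00 in NCI-H2087 NKX2-1 and 3.09 in NCI-H2087 H3K4me3), and the threshold was read from these values. Fold, p and q are the authors' values. They were used to rank, filter and describe peaks within a list and, for fold and p, to solve for the local background described below. A peak list depends on depth, antibody and threshold, so a missing peak is not a missing protein, and longer lists overlap more with any other list.

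Peaks on chromosomes 1 to 22 and X were analysed. Peaks on Y and on unplaced or other contigs were left out, 0.0610% to 0.502% of a list. A region was shared by a pair of lists when their peaks overlapped by at least 1 bp. For sharing between lines the peaks of the 4 lines were merged, and a line counted as bound when one of its peaks overlapped the merged region. Jaccard indices were taken over base pairs. The gene table used was that of GRCh38.p14 with 19974 protein-coding genes on these chromosomes. It gives gene starts and ends without strand, so the transcription start could not be told from the gene end. Wherever the design spoke of a start site, either annotated end of a protein-coding gene was used, within 1 kb, or 5 kb as the alternative. All genes of the fixed lists were found in the table, PIFO under its current symbol CIMAP3. The motif scan planned in the design needs a genome sequence and was not run.

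The peak caller writes fold as (pileup + 1) / (background + 1) and a Poisson p of the same 2 numbers. Solving both for a whole-number pileup gave the pileup and the local background of at least 99.96% of the peaks of each list within 0.01 of the written −log10 p. Chance alone would give 2.38% to 5.95%. The lowest background of a list is its genome-wide level and serves as its relative depth. The background near 14q13 is the median over peaks within 1 Mb of the NKX2-1 gene divided by the median over all peaks of the library. Bins of 1 Mb needed at least 5 peaks. Whether input libraries set this background is not given in the sources used here. A background at the genome-wide level is the lowest the caller writes, so low values are upper limits.

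The unit of comparison was the cell line. H3K27ac and H3K4me1 at sites bound in 1 line were tested by permuting the 4 line labels of the histone libraries (24 assignments, one-sided, Benjamini-Hochberg over 2 tests). Paired differences over the 4 lines used an exact two-sided sign-flip permutation, whose smallest p is 0.125. Overlap with H3K27ac was set against 100 random placements of the peaks on the same chromosome per line. Co-occupancy in NCI-H2087 is the observed number of regions with both factors over the number expected from their totals in the union of the 11 lists. These regions are merged over all 11 lists, so 2 factors can share a region without overlapping peaks. Gene lists were compared, by the mean number of regions bound in 4 lines within 50 kb of either gene end, with 10000 random lists matched on quintiles of gene length and of gene density, as a description of these libraries. Members of a list that lie next to each other share regions, which the random lists do not match. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only.

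Gene lists, tests, alternatives and the rule for named genes were set before the data were examined. The rule takes the 12 genes with the most regions bound in 4 lines (each region to its nearest gene within 50 kb). For each line it takes the 5 genes with the most private regions and no region bound in 4 lines, and the 5 genes with private H3K27ac at a gene end and the longest acetylated length within 25 kb. It adds the 10 regions of NCI-H2087 bound by 6 factors with the highest NKX2-1 fold, the 3 leading members of each list, and a fixed set of loci. Some genes that the rule takes are not reported here. Ties went to the higher total of NKX2-1 peaks and then to alphabetical order. Alternatives were peaks with −log10 q of at least 10, the 20000 peaks of highest fold, 500 bp windows on summits, summits within 200 bp, regions over 1 kb from gene ends, other windows, and leaving out each line. Added after seeing the data were lists of the 5000 strongest peaks, gene ends with H3K4me3 in NCI-H2087, sites compared within 10 equal classes of NKX2-1 fold, bins where the background of the 4 lines lay within 1.25 times, and the stricter q for the 12 shared genes.

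Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Sharing, co-occupancy, the background, the permutation tests and the gene list percentiles were tested on simulated data with known answers. For the sharing of regions, 0 of the class counts over 20000 simulated places were wrong, and for the background, the pileup of 100% of 4984 simulated peaks was recovered. For H3K27ac at private sites, 5.50% of 1000 simulated tables without an effect fell below 0.05, and for the gene lists, 4.50% of 200 random lists lay above percentile 95. The simulated places lay far apart, so the joining of neighbouring peaks into 1 region was not tested. The simulated gene lists held no neighbouring genes that share regions.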

Results

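Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in 4 untreated human lung adenocarcinoma cell lines, NCI-H2087, NCI-H358, NCI-H441 and HCC364. The title of the series names the amplified dosage of NKX2-1, a homeobox transcription factor of lung and thyroid development, as its subject. NKX2-1, the active chromatin mark H3K27ac and the enhancer-associated mark H3K4me1 were profiled in all 4 lines. In NCI-H2087 the list was extended to 11 antibodies by the forkhead factors FOXA1 and FOXA2, SOX2, the AP-1 subunit c-Jun, the histone acetyltransferase EP300, RNA polymerase II, the promoter mark H3K4me3 and the insulator protein CTCF. Each combination of line and antibody is 1 library with its own peak list, so differences between lines have no replicate check and no p-value is given across peaks or genes. Binomial intervals below are exact 95% intervals and cover counting error only.

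The NKX2-1 lists held 75657 peaks in NCI-H2087, 75747 in NCI-H358, 90578 in NCI-H441 and 87160 in HCC364, with median widths of 471 to 507 bp. They covered 45.2, 44.5, 54.9 and 49.1 Mb of the genome. H3K27ac lists held 51482, 47136, 47228 and 56384 peaks in the same order, and H3K4me1 lists 91807, 113605, 99062 and 121789. Among the other NCI-H2087 lists, FOXA2 (82111 peaks), FOXA1 (67706) and CTCF (61072) were long. RNA polymerase II (26019), c-Jun (23360), H3K4me3 (22512), SOX2 (9262) and EP300 (7406) were shorter. Read totals were not used here, but the lowest background solved from the peak values gives a relative depth per library. It was 2.65, 2.72, 2.85 and 2.54 fragments for NKX2-1 in NCI-H2087, NCI-H358, NCI-H441 and HCC364, a narrow range. In NCI-H2087 it was lowest for c-Jun (1.13) and EP300 (1.52) and highest for H3K4me3 (4.19) and FOXA2 (4.14), so the c-Jun and EP300 libraries were the shallowest of the 11 by this measure.

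The first comparison asks how far NKX2-1 binding is shared between lines. Merging the 4 NKX2-1 lists gave 145799 regions, of which 32534, or 22.3% (22.1 to 22.5%), were bound in all 4 lines (14.6% with the 20000 strongest peaks of each list). A further 24956 regions were bound in 3 lines, 29702 in 2 lines and 58607 in 1 line only. Of the regions found in 1 line, 20410 belonged to HCC364, 15244 to NCI-H441, 13260 to NCI-H358 and 9693 to NCI-H2087. H3K27ac was found in all 4 lines at 23.9% of its 84925 regions and H3K4me1 at 21.2% of its 174263 regions. NCI-H2087 and NCI-H441 were the closest pair for each of the 3 antibodies, with base-pair Jaccard indices of 0.470 for NKX2-1, 0.523 for H3K27ac and 0.454 for H3K4me1. NCI-H358 and HCC364 were the most distant pair for each, with 0.351, 0.371 and 0.309. The mean over the 6 pairs of lines was 0.40 ± 0.040 (SD) for NKX2-1, 0.441 ± 0.061 for H3K27ac and 0.365 ± 0.056 for H3K4me1. H3K27ac exceeded NKX2-1 in 5 of the 6 pairs, but with 500 bp windows on summits in place of whole peaks the order of the means turned. They were then 0.371 for NKX2-1, 0.237 for H3K27ac and 0.161 for H3K4me1.

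**Figure D1:**
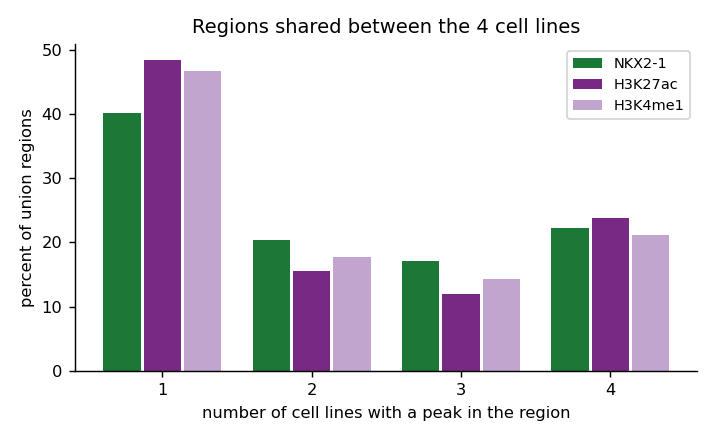
Percent of union regions (y axis) found in 1, 2, 3 or 4 of the cell lines (x axis), for NKX2-1, H3K27ac and H3K4me1, with 1 library per line and antibody. NKX2-1 regions bound in all 4 lines made up 22.3% of the union, against 23.9% for H3K27ac and 21.2% for H3K4me1.

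Each NKX2-1 region was given to the nearest protein-coding gene within 50 kb of one of its annotated ends. SMAD3, a transducer of TGF-beta signals on chromosome 15 (67065602 to 67195169), had the most shared regions, 18 of its 39. MYH9, the heavy chain of a non-muscle myosin on chromosome 22 (36281280 to 36387967), had 17 of 47, and ATXN1 had 15 of 21. MET, the hepatocyte growth factor receptor on chromosome 7 (116672196 to 116798377), had 14 of 31, as many as PLB1, which had 14 of 25. ERRFI1, an inhibitor of the EGF receptor, TPRG1 and ANXA2, a calcium-dependent membrane-binding protein, had 13 each. NRP2, a co-receptor for semaphorins and VEGF, SH3RF1, NTN4 and GNG12 had 12 each.

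Of the gene groups fixed in advance, epithelial keratins and junction proteins lay closest to shared NKX2-1 binding. Their 14 members had on average 7.57 shared regions within 50 kb, where the median random list matched on gene length and gene density had 2.57 (percentile 100 of 10000 random lists). KRT8 and KRT18 lie side by side and share regions, which the random lists do not match. KRT8 and KRT7, keratins of simple epithelia, had 12 shared regions each, CDH1 (E-cadherin) 11 and KRT19 10. All 14 had at least 1, and 10 carried H3K27ac within 1 kb of an annotated end in all 4 lines. The 12 receptor tyrosine kinase and MAPK genes averaged 6.08 (percentile 100), led by MET with 14, PHLDA1 with 11 and ERBB3 with 10. The 9 AP-1 genes averaged 5.22 (percentile 99.86), with 9 near ATF3, 8 near FOSL1 and 7 near FOS. The 9 neighbours of NKX2-1 at 14q13 averaged 5.00, led by SFTA3 with 8 and by NKX2-1, SLC25A21 and NFKBIA with 7 each, but they lie next to each other and share regions, so no percentile is given. Housekeeping genes, taken as a comparator, also stood high, with a mean of 4.10 and a percentile of 99.6, and among them RPLP0 had 7 and B2M 6. Over all 19974 protein-coding genes the mean was 2.75, and 79.8% had at least 1 shared region.

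Genes of the mature alveolar cells gave a mixed picture. The 10 alveolar type 1 genes averaged 4.00 shared regions (percentile 97.3), with 7 near GPRC5A, 7 near CAV1 and 6 near HOPX. The 15 alveolar type 2 genes averaged 3.27 (percentile 84.5), and with regions bound in at least 1 line in place of all 4 the percentile was 99.9, while with a 10 kb window it was 71.2. MUC1 had 10 shared regions, CTSH 7 and SFTPB 6. The surfactant gene SFTPB had 13, 8, 20 and 16 NKX2-1 regions in NCI-H2087, NCI-H358, NCI-H441 and HCC364, and NAPSA, an aspartic protease of type 2 cells, had 6, 9, 11 and 13. SFTPA1 had 7, 0, 9 and 4, no region shared by all 4 lines, and carried H3K27ac at a gene end in NCI-H2087 and NCI-H441 only. SFTPC had 3, 16, 9 and 15 with 3 shared, and ABCA3, a lipid transporter of type 2 cells, had 5, 7, 10 and 3 with 1 shared. The 12 lung and foregut transcription factors averaged 2.67 (percentile 92.4, or 99.96 with regions bound in at least 1 line), led by NKX2-1 with 7 and by SOX9 and TFAP2A with 4 each. FOXA1 itself had 13, 13, 16 and 2 regions, and SOX2 7, 6, 7 and 4. FOXA2 had 3, 1, 2 and 5 with none shared.

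Groups of other lineages varied. Basal and squamous genes averaged 4.10 (percentile 95.2), led by KRT15 with 11, DSG3 with 9 and PKP1 with 5, although 6 of the 10 carried H3K27ac at a gene end in no line. KRT15 (41513745 to 41518890 on chromosome 17) lies beside KRT19 of the epithelial group (41523617 to 41528308), so the 2 genes share regions. With a 10 kb window their percentile was 71.5. TP63 had 12, 16, 14 and 5 NKX2-1 regions over the 4 lines and carried H3K27ac at a gene end in NCI-H358 only. Ciliated genes stood at percentile 63.8, led by DNAH5 with 8, RSPH1 and CAPS with 5 each. Mesenchymal genes stood at 51.3, led by VIM and COL1A1 with 6 each and FN1 with 3, and thyroid genes at 50.4, led by TSHR with 6, SLC5A5 with 5 and PAX8 with 4. Airway secretory, immune and gastric, intestinal and liver genes were all at percentile 32.4, but with a 10 kb window they were at 80.3, 39.3 and 16.2. With regions bound in at least 1 line airway secretory genes were at 18.7 and immune genes at 16.7. With a 10 kb window thyroid genes were at 20.3 and mesenchymal genes at 19.8. Among their leading members were AGR2 with 6, BPIFB1 and SPDEF with 3 each, then IL7R, CD3E and CD14 with 4 each, then LGALS4 with 7 and FGA with 4. HNF4A, a hepatic and gastrointestinal regulator, had 4, 4, 5 and 6 regions with 2 shared, and carried H3K27ac at a gene end in none of the lines. Neuroendocrine genes stood at percentile 11.8 (3.11 with a 10 kb window and 4.82 with regions bound in at least 1 line), led by SYP with 5, DLL3 with 4 and UCHL1 with 2. Erythroid genes were at 6.47 (41.3 and 3.99 under the same changes), led by KLF1 and EPOR with 5 each and GATA1 with 3. The group of loci named in every case, which repeats members of other groups, averaged 4.50. In it KRT7 had 14, 17, 21 and 15 regions, ERBB3 14, 11, 13 and 12, EGFR 14, 6, 12 and 15 and MYC 11, 11, 9 and 7. LMO3, a LIM-domain partner of transcription factors, had 22, 5, 16 and 26 with 3 shared, and NKX2-8, a homeobox neighbour of NKX2-1, had 7, 6, 11 and 6 with 4 shared.

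Private binding, meaning regions bound in 1 line at genes without any region bound in all 4, was counted per line. In HCC364, DPYSL2, a regulator of microtubules in axons, had 14 private regions among the 19 assigned to it, ZBTB18, a zinc finger repressor, 10 of 13, KIRREL1 and the basal keratinocyte factor BNC1 9 each, and SPTBN1 8. Genes of this kind in NCI-H358 included ZNF565 with 9, and GLI3, a Hedgehog pathway factor, PTPRU and ZNF658 had 7 each. In NCI-H2087 the leading genes were ARHGAP28 with 7, PRR5L, WIPF3 and FAM78B with 6 each and CYRIA with 5. In NCI-H441, LOC124904304 and the homeobox gene IRX2 had 6 private regions each, and LOC110384692, C14orf132 and the corepressor gene BCOR had 5 each.

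The next comparison asks whether sites bound in 1 line carried active or enhancer marks in that same line. They did in each of the 4 lines. H3K27ac overlapped 36.3% of HCC364-only sites in HCC364 itself, against 11.4% in NCI-H2087, 10.8% in NCI-H358 and 9.69% in NCI-H441. For NCI-H358-only sites the share was 35.0% in NCI-H358 and between 9.06% and 11.0% in the other lines, for NCI-H2087-only sites 27.3% against 9.83% to 11.1%, and for NCI-H441-only sites 23.2% against 7.70% to 8.88%. The mean was 30.4% in the line that was bound and 10.0% in the others, a difference of 20.4 percentage points ± 5.57 (SD over n = 4 lines, higher in 4 of 4). H3K4me1 was more widespread, at 56.5% in the bound line against 21.4% elsewhere, a difference of 35.0 points ± 8.60 (n = 4, higher in 4 of 4) that was 22.7 points with the 20000 strongest peaks. In an exact permutation of the line labels of the histone libraries, one-sided, both differences gave p = 0.0417 (n = 4 lines), the smallest that 24 assignments allow, and 0.0417 after Benjamini-Hochberg adjustment over the 2 tests. With any 1 line left out the differences were 18.9 to 23.9 points for H3K27ac and 32.0 to 37.2 for H3K4me1, and the exact permutation p was 0.167, the smallest that 3 lines allow.

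**Figure D2:**
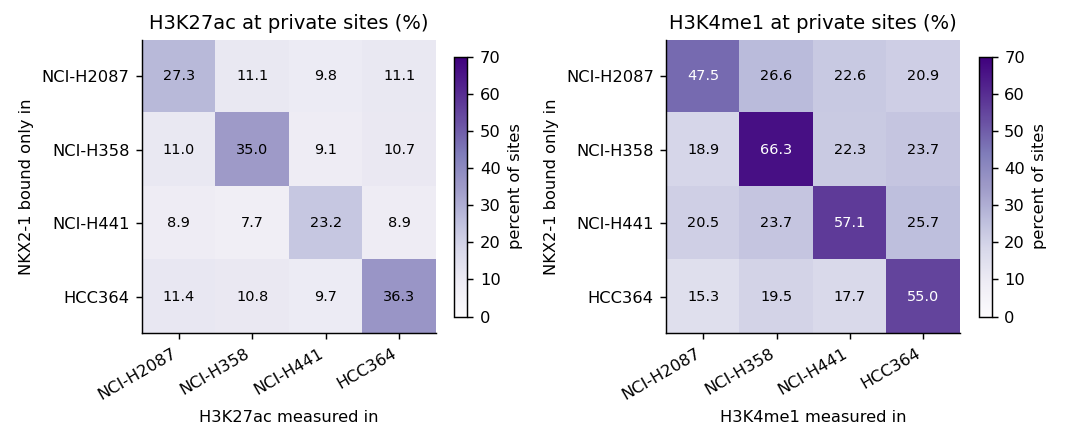
Percent of NKX2-1 sites bound in 1 line only (rows) that overlapped H3K27ac (left) or H3K4me1 (right) in each line (columns), with 1 library per line and antibody. In every row the highest share is on the diagonal, where the mark was measured in the bound line, up to 36.3% for H3K27ac and 66.3% for H3K4me1.

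Sites bound in all 4 lines carried H3K27ac far more often than private sites. The shared sites overlapped H3K27ac in 67.8% ± 1.71 of cases (SD, n = 4 lines), with 69.95% in NCI-H2087, 65.8% in NCI-H358, 67.8% in NCI-H441 and 67.9% in HCC364. Sites bound in 1 line overlapped it in 30.4% ± 6.25 of cases, a difference of 37.4 points ± 7.23 that was present in 4 of 4 lines and was 20.6 points with the 20000 strongest peaks. The shares rose in steps with the number of lines bound, for example 27.3%, 38.0%, 47.9% and 69.95% in NCI-H2087. H3K4me1 differed less, with 75.9% ± 3.97 against 56.5% ± 7.77. An exact two-sided sign-flip permutation over the 4 lines gave p = 0.125 for both marks, the smallest that n = 4 allows, so it cannot reach 0.05. Sites bound in 4 lines also had stronger peaks, with a median NKX2-1 fold of 13.7 against 6.51 in HCC364 and 10.9 against 6.10 in NCI-H2087. They are merged from the peaks of 4 lines and so can be wider, which raises overlap with any list. Region width was not matched. In NCI-H2087 the shares at shared and private sites were also 28.4% and 10.1% for CTCF and 27.8% and 12.0% for H3K4me3.

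Taking all NKX2-1 peaks of a line, 50.4% ± 2.76 (SD, n = 4 lines) overlapped H3K27ac and 65.7% ± 4.16 overlapped H3K4me1 of that line. Both marks were present at 38.5% ± 1.17, H3K4me1 without H3K27ac at 27.2% ± 3.65, and neither mark at 22.3% ± 2.5. Peaks placed at random on the same chromosome overlapped H3K27ac in 3.41% to 4.44% of cases over 100 placements per line, which put the observed overlap 11.6 to 14.7 times above it. In the other direction, 78.5% of the H3K27ac peaks of NCI-H441 held an NKX2-1 peak, and 66.2% to 68.9% in the other lines. NKX2-1 lay mostly away from annotated gene ends. On average 12.5% ± 1.01 of its peaks lay within 1 kb of an annotated end of a protein-coding gene, against 24.2% ± 0.928 for H3K27ac, and the share was lower in 4 of 4 lines by a mean of 11.7 points (11.1% against 25.2% in NCI-H441). Within 5 kb the NKX2-1 share was 24.2%, and within 1 kb of ends that carried H3K4me3 in NCI-H2087 the shares were 10.3% for NKX2-1 and 21.7% for H3K27ac. For the share within 1 kb an exact two-sided sign-flip permutation gave p = 0.125 (n = 4 lines), the smallest possible. By overlap with H3K4me3 itself, the NCI-H2087 shares were 20.4% for NKX2-1 peaks and 33.9% for H3K27ac peaks.

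H3K27ac at gene ends separated the lines at smaller sets of genes. HCC364 had 324 genes with H3K27ac within 1 kb of an annotated end and none within 5 kb in the other 3 lines, NCI-H358 had 177, NCI-H2087 174 and NCI-H441 80. Of these HCC364 genes, IGSF23 and WDR86 had the most H3K27ac-covered length within 25 kb of a gene end, 23.2 kb each. NFIC, a nuclear factor I gene, had 22.1 kb, KANK2 21.5 kb and the cytochrome P450 gene CYP2S1 20.3 kb. This length counts all H3K27ac peaks of the line in the window and is not that of a single domain. Only the 5 kb around the gene ends had to lack the mark in the other lines, so part of it may be shared with them. In NCI-H358 the leading genes by this length were the collagen prolyl hydroxylase gene P3H2 (17.7 kb), FXYD1 (15.6 kb), SUSD3 (15.0 kb), PLCB1 (11.7 kb) and BST1 (11.1 kb). In NCI-H2087 they included the homeobox genes HOXB8 (14.8 kb) and HOXB9 (12.7 kb), which had 7 and 6 NKX2-1 peaks there, 5 and 4 in HCC364 and none in NCI-H358 or NCI-H441. HOXB8 and HOXB9 lie side by side on chromosome 17, so their windows overlap and can count the same peaks. ANKRD18B (15.1 kb), DMGDH (13.2 kb) and ANKUB1 (11.7 kb) completed the NCI-H2087 group. NCI-H441 had shorter covered lengths, at the transglutaminase gene TGM5 (9.56 kb), the semaphorin receptor gene PLXND1 (9.18 kb), AZGP1 (9.08 kb), PCDHAC2 (7.55 kb) and the cytokine gene IL17C (7.07 kb). TGM5 had 12 NKX2-1 peaks in NCI-H441 and 2 to 7 in the other lines. Not all of these genes had the most NKX2-1 peaks in their acetylated line. P3H2 had 5 in NCI-H358 and 6 to 8 elsewhere, and BST1 10 in NCI-H358 and 9 to 11 elsewhere.

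The 11 NCI-H2087 libraries show which factors lay at NKX2-1 regions. Over the full lists almost all SOX2 and EP300 regions were also NKX2-1 regions, at 96.7% (96.3 to 97.0%) and 97.7% (97.3 to 98.0%), and so were 92.2% (91.8 to 92.6%) of c-Jun regions. Regions merged over the 11 lists can join factors whose own peaks do not overlap. With summits within 200 bp of an NKX2-1 summit the shares were 89.9% for SOX2, 84.3% for EP300 and 82.9% for c-Jun. With at most the 20000 strongest peaks of each list they were 69.7% for SOX2, 67.4% for EP300 and 52.8% for c-Jun, and with 5000 peaks 37.6%, 38.8% and 33.8%. FOXA1 regions held NKX2-1 in 62.2% of cases, FOXA2 regions in 55.3% and CTCF regions in 28.2%. Against the overlap expected if NKX2-1 were independent of the other factor over the 168383 regions of the 11 lists, the observed overlap was 2.59-fold for EP300, 2.56-fold for SOX2, 2.45-fold for c-Jun, 1.65-fold for FOXA1, 1.47-fold for FOXA2 and 0.746-fold for CTCF. By the same rule it was 2.02-fold for H3K27ac, 1.73-fold for RNA polymerase II, 1.61-fold for H3K4me1 and 1.5-fold for H3K4me3. NKX2-1 held 37.7% of the 168383 regions, so these folds have an upper limit, reached when every partner region holds NKX2-1. EP300, SOX2 and c-Jun stood close to that limit. Every region holds a peak of some list, so a low fold, as for CTCF, does not show avoidance relative to the genome. Seen from the NKX2-1 side, 63.8% of its regions held FOXA2, 58.7% FOXA1, 30.2% c-Jun, 26.2% CTCF, 13.3% SOX2 and 10.4% EP300. This order changed with list length. With at most the 20000 strongest peaks the shares were 49.5%, 48.4%, 51.4%, 7.02%, 32.7% and 24.5% in the same order. With 5000 peaks they were 34.3%, 31.5%, 33.3%, 1.18%, 37.6% and 38.0%. The folds depend on list length. With the 5000 peaks of highest fold from each list they ranged from 1.74 for FOXA1 to 2.16 for EP300, and CTCF fell to 0.0645.

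Within NCI-H2087 the partners differed between NKX2-1 sites bound in all 4 lines and sites bound in NCI-H2087 alone. FOXA2 was found at 63.2% (62.6 to 63.7%) of the 32534 shared sites and at 61.2% (60.2 to 62.1%) of the 9693 private sites, and SOX2 at 13.9% (13.5 to 14.3%) and 12.7% (12.1 to 13.4%). FOXA1 was at 60.7% and 52.0%. Compared within 10 classes of NKX2-1 fold, chosen after seeing the data, the direction turned for these 3 factors, to −9.83 points for FOXA1, −15.9 for FOXA2 and −9.50 for SOX2 at shared against private sites. Without this matching c-Jun was at 44.0% (43.4 to 44.5%) of shared and 5.78% (5.32 to 6.26%) of private sites, and EP300 at 16.7% (16.3 to 17.2%) and 1.11% (0.915 to 1.34%). Within the classes of fold the differences fell from 38.2 to 20.2 points for c-Jun and from 15.6 to 6.63 for EP300, and kept their direction. Region width was not matched. RNA polymerase II was at 36.7% and 11.1%, and CTCF at 28.4% and 10.1%. Sites bound only in other lines held c-Jun in 1.97%, FOXA2 in 11.9% and SOX2 in 0.0753% of cases.

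**Figure D3:**
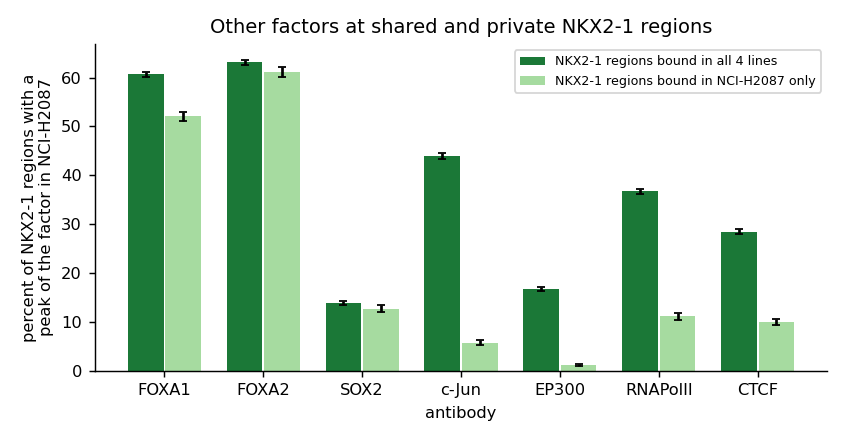
Percent of NKX2-1 regions that overlapped a peak of each antibody in NCI-H2087 (y axis), for regions bound in all 4 lines and regions bound in NCI-H2087 only, with exact 95% binomial intervals as error bars and 1 library per antibody. FOXA2 stood at 63.2% and 61.2% in the 2 kinds of region, c-Jun at 44.0% and 5.78%.

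Of the NKX2-1 peaks of NCI-H2087, 2445 overlapped peaks of all 5 of FOXA1, FOXA2, c-Jun, EP300 and SOX2, or 3.23%, and 24278 overlapped none of the 5. The strongest of the 2445 by NKX2-1 fold lay on chromosome 3 (108282679 to 108283663), between genes and 13377 bp from an end of HHLA2, an immune checkpoint ligand gene, with a fold of 172. The next lay 105784 bp from FEM1C on chromosome 5 (fold 125). The third lay on chromosome 14 (34137569 to 34140085), 187752 bp from EGLN3, an oxygen-sensing prolyl hydroxylase gene (fold 120). Others of the first 10 were nearest to FBF1 (fold 118), LOC124905366 (117), DNAH11 (113, inside the gene), NID1 (113), PCDHA1 (109, inside the gene) and ATP10B (106).

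The last comparison concerns the NKX2-1 locus itself, on chromosome 14 (36516397 to 36520232, GRCh38). The background that the peak caller assigned to peaks within 1 Mb of the gene, relative to the median of the library, was 2.46 ± 0.162 over the 11 NCI-H2087 libraries and 2.12 ± 0.048 over the 3 NCI-H441 libraries. It was 1.46 ± 0.030 over the 3 NCI-H358 libraries and 0.817 ± 0.029 over the 3 HCC364 libraries (SD over libraries of 1 line, which share their cells and so are not biological replicates). In HCC364 52.7% of the NKX2-1 peaks in the window sat at the lowest background the caller allows, so the HCC364 value is an upper limit. Against the chromosome 14 median, the NKX2-1 library stood at 1.94 in NCI-H2087, 1.92 in NCI-H441, 1.12 in NCI-H358 and 1.00 in HCC364. The HCC364 value was therefore not particular to the locus, and most of the NCI-H358 value was shared with the rest of the chromosome. In NCI-H441 the background was 1.41 between 35000001 and 36000000, 2.17 and 2.23 in the next 2 bins of 1 Mb, which hold NKX2-1 and FOXA1, 2.08 between 39000001 and 40000000, and 1.41 again between 45000001 and 46000000, with no value between 40000001 and 45000000, so the right edge is not resolved. In NCI-H2087 it was between 1.86 and 2.35 in the bins with a value from 26000001 to 46000000. It stood at 2.96 between 48000001 and 49000000 and at 1.12 in the next bin.

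**Figure D4:**
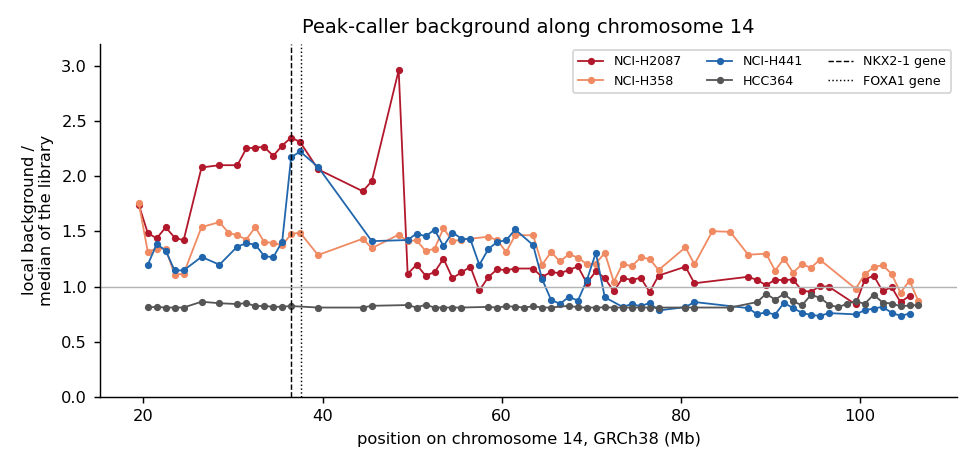
Local background of the peak caller divided by the median of the library (y axis, mean over the NKX2-1, H3K27ac and H3K4me1 libraries of a line) in 1 Mb bins along chromosome 14 of GRCh38 (x axis, Mb), with bins of fewer than 5 peaks in any of the 3 libraries left out. At the NKX2-1 bin the lines stood at 2.35 (NCI-H2087), 1.48 (NCI-H358), 2.17 (NCI-H441) and 0.823 (HCC364).

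Within the same 1 Mb on each side of the gene, HCC364 had 26 H3K27ac peaks and the other lines 65 (NCI-H2087), 65 (NCI-H358) and 67 (NCI-H441). NKX2-1 peaks numbered 93 in HCC364 and 133, 129 and 140 in the others, and H3K4me1 peaks 104 against 140, 177 and 145. The NKX2-1 gene carried H3K27ac within 1 kb of an annotated end in all 4 lines, as did SFTA3, MBIP, NFKBIA and SLC25A21, while PAX9 carried it in NCI-H2087 and NCI-H441 and NKX2-8 in NCI-H2087 and NCI-H358. NKX2-1 regions within 50 kb of its own gene numbered 16, 10, 19 and 15 in NCI-H2087, NCI-H358, NCI-H441 and HCC364.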

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

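The tests below were chosen before their results were seen, except the comparison of the list lengths of HCC364, the one over all pairs of lines, and the one of c-Jun with SOX2 at 1 list length. The classes of NKX2-1 fold and the bins of even background were added after the data were seen, with their bounds set before those 2 results. Of 47 values compared over the 4 lines, each line being 1 library, 4 had 1 line standing apart by Dixon's ratio, where chance alone would give 2.35.

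The H3K27ac peaks within 1 Mb of NKX2-1 numbered 26 in HCC364 against 65 to 67 in the other 3 lines, or 0.396 of their mean. The whole H3K27ac list of HCC364 was longer than the others, at 1.16 times their mean, which argues against a short list. Copy number was the other technical explanation, since the HCC364 background there was 0.412 of the mean of the other lines and fewer fragments give fewer calls. In the 6 windows of 2 Mb outside chromosome 14 with the lowest HCC364 background relative to the other lines (down to 0.480) the median peak ratio was 0.883. The deepest holds MYC, and within 1 Mb of MYC the NCI-H2087 background was 3.48 times the library median. The HCC364 background there was not below its library median. NCI-H2087 was also raised in the other windows on chromosome 8 and in that on chromosome 12. There the low ratio need not mean a low HCC364 background, so these windows cannot show what one does to peak calls. At 14q13 the other lines were raised too, at 2.46 (NCI-H2087), 1.46 (NCI-H358) and 2.12 (NCI-H441) times their library medians. HCC364 stood at 0.817, so the low ratio there is only in part a low HCC364 background. Over the 6 windows the peak ratio was highest in the MYC window (0.966) and lowest in those on chromosome 5 (0.702 and 0.806). Over all pairs of lines, 17 pairs of windows had a background ratio of at most 0.45. Their median relative ratio was 0.891 (95% interval 0.684 to 0.964), the lowest being 0.386 against 0.354 at 14q13. None of the 6 windows is as deep in background as 14q13 and the interval over the pairs reaches below the bound set for excluding copy number, so copy number and a true loss of active sites at 14q13 in HCC364 cannot be told apart here, and a biological difference between the lines was not tested.

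In NCI-H2087, c-Jun and EP300 lay mainly at NKX2-1 sites shared by 4 lines, while FOXA2 and SOX2 lay at shared and NCI-H2087-only sites in like shares. Compared within 10 classes of NKX2-1 fold, the c-Jun difference went from 38.2 to 20.2 percentage points (95% interval 19.5 to 21.2). The EP300 difference went from 15.6 to 6.63 (6.21 to 7.06), so peak strength took part of both. The intervals come from resampled sites and not from replicate libraries. The remainder was 52.9% of the full difference for c-Jun, just past the bound set in advance. For EP300 it was 42.4%, between the bounds. By these bounds strength is argued against as the whole cause for c-Jun, by a small margin, and stays open for EP300. Matched within the same classes of fold, the differences of FOXA1 (from 8.62 to −9.83 points), FOXA2 (from 1.99 to −15.9) and SOX2 (from 1.19 to −9.50) turned to fewer at shared sites. Away from gene ends the c-Jun difference was 44.0 points, which argues against promoters as its source. Regions bound in 4 lines merge more peaks, and their width was not matched. With lists as long as that of EP300, the strongest peaks by fold, the FOXA2 share at private sites was 47.7% of that at shared sites, so list length may account for part of the contrast with FOXA2, but SOX2 stood 30.3 times above c-Jun by this measure at 1 list length and 6.96 times over the full lists, and no biological explanation was tested.

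Sites bound in 1 line carried H3K27ac more often in that line, by 20.4 percentage points. In 469 bins of 1 Mb where the background of the 4 lines was nearly even, the difference was 21.9 points ± 7.12 (SD over 4 lines), which argues against gains of copies as the cause. The background cannot fall below its genome-wide level, so a loss of copies can pass as even and was not tested. Unspecific pull-down of acetylated chromatin would raise other antibodies too, and CTCF was the comparator set in advance. In NCI-H2087 the share of CTCF at regions acetylated in NCI-H2087 alone was 0.945 times (0.877 to 1.02) that at regions acetylated in 1 other line alone. NKX2-1 stood at 3.19 times, FOXA1 at 3.22, FOXA2 at 2.96, c-Jun at 3.82 and SOX2 at 9.66. Only CTCF was not raised, and the test cannot tell true binding of the others from unspecific pull-down, so it does not exclude the latter. A hypothesis left open is that line-specific binding and acetylation go together at these sites, with neither order between them tested, and in the other 3 lines the pull-down test was not run.

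The median width of H3K27ac peaks was 944 bp in NCI-H2087 and 1060 to 1069 bp in the other lines. For H3K4me1 it was 913 bp in NCI-H441 and 798 to 815 bp elsewhere. The lowest H3K4me1 background was 2.52 fragments in NCI-H358 and 2.77 to 2.82 in the other lines.

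Outside the chromosomes analysed, peaks were listed on the Epstein-Barr virus contig of the reference in NKX2-1 libraries only. NCI-H441 NKX2-1 had 1, with a fold of 110.8 (pileup of 426 fragments, place 10 in its list by fold), and HCC364 NKX2-1 had 2, the stronger with a fold of 390.9 (1381 fragments), the highest of that list, above 229.9 for the highest human peak. All other lists had 0, and input libraries were not analysed here.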

How the results depend on the processing

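The order of the H3K27ac and NKX2-1 Jaccard means turned with summit windows, and within 10 classes of NKX2-1 fold FOXA1, FOXA2 and SOX2 turned to being less frequent at shared than at NCI-H2087-only sites. Airway secretory genes went from below to above random lists with 10 kb, neither past a threshold. Of 153 alternative values over 49 results, 83 stayed within the spread or, where a test or percentile can pass its threshold, on the same side of it, 56 moved beyond the spread, 9 lost their threshold and 5 passed one, and 12 of the 12 most shared genes stayed within 1.5 times at the stricter q, an alternative chosen after seeing the data like the 5000-peak lists below. For moved values the cause was not tested. Regions bound in all 4 lines were 21.5% of the union at −log10 q of at least 10, 14.6% with the 20000 strongest peaks and 20.3% with summit windows. Leaving out 1 line, the share bound in all 3 others ranged from 26.7% to 32.4%, since 3 lines are an easier condition. Mean Jaccard indices moved to 0.323 for NKX2-1 and 0.241 for H3K4me1 with the 20000 strongest peaks, and to 0.237 for H3K27ac and 0.161 for H3K4me1 with summit windows, which drop peak width. NKX2-1 peaks with H3K27ac went to 45.4% at the stricter q, 42.3% with the 20000 strongest peaks and 38.5% when the summit had to lie inside. Co-occupancy with NKX2-1, in the order FOXA1, FOXA2, c-Jun, EP300 and SOX2, was 1.52, 1.34, 2.34, 2.44 and 2.47 at the stricter q, 1.88, 1.92, 2.09, 2.67 and 2.76 with the 20000 strongest peaks, 2.06, 1.83, 3.21, 3.26 and 3.48 with summits within 200 bp, 1.67, 1.48, 2.56, 2.76 and 2.69 away from gene ends, and 1.74, 1.89, 1.88, 2.16 and 2.09 with 5000 peaks, while CTCF was 0.618, 0.261, 0.755, 0.651 and 0.0645. With 5000 peaks the gap between FOXA2 and c-Jun closed. Basal and squamous genes fell to percentile 71.5 with 10 kb, alveolar type 2 genes to 71.2, gastric, intestinal and liver genes to 16.2, thyroid genes to 20.3 and mesenchymal genes to 19.8, while airway secretory genes rose to 80.3 and erythroid genes to 41.3. Alveolar type 2 genes rose to 99.86 and lung and foregut factors to 99.96 with regions bound in at least 1 line, where erythroid genes were at 3.99 and neuroendocrine genes at 4.82 (3.11 with 10 kb). The 14q13 background of the NKX2-1 library was 2.14 (100 kb) and 1.94 (against chromosome 14) in NCI-H2087, 1.24 and 1.12 in NCI-H358 and 1.92 and 1.92 in NCI-H441, and 1.00 against chromosome 14 in HCC364. With a line left out, H3K27ac at private sites differed by 18.9 to 23.9 points and H3K4me1 by 32.0 to 37.2, each with an exact permutation p of 0.167, the smallest that 3 lines allow. With all 4 lines the H3K27ac difference was 18.0 to 21.9 points over its alternatives, and H3K4me1 went from 35.0 to 22.7 points with the 20000 strongest peaks. The H3K27ac difference between shared and private sites was 20.6 points with the 20000 strongest peaks, 34.7 at the stricter q and 34.6 away from gene ends. It was 30.1 to 33.2 with a line left out, where shared and private sites are defined over 3 lines, which is another contrast. Within 10 classes of NKX2-1 fold it was 19.6 points or more per line (mean 29.4 ± 8.71, chosen after seeing the data). NKX2-1 peaks near gene ends were 9.26% with the 20000 strongest peaks, 24.2% with 5 kb and 10.3% at ends with H3K4me3 in NCI-H2087 (chosen after seeing the data). The planned motif scan was not run. There is 1 library per line and antibody and no read totals were used. By their lowest background c-Jun and EP300 were the shallowest libraries, and the effect of depth on their weak sites was not tested.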

Other observations

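The values in the first 2 paragraphs were chosen after seeing the data. The local background also stood apart at other genes, given as the mean over the NKX2-1, H3K27ac and H3K4me1 libraries of a line (SD, n = 3 libraries of the same cells). In NCI-H2087 it was 5.60 ± 0.543 times the library median within 1 Mb of CDK4, a cell cycle kinase gene on chromosome 12, and 3.48 ± 0.154 at the MYC oncogene, where NCI-H358 had 1.76 ± 0.030, NCI-H441 1.39 ± 0.054 and HCC364 1.1 ± 0.074. At CDK4 the other lines had 0.873, 1.08 and 1.04. In NCI-H441 it was 1.91 ± 0.052 at MET and 2.22 ± 0.078 at FOXA1, the neighbour of NKX2-1 on chromosome 14. HCC364 had 1.46 ± 0.021 at MET and 0.825 ± 0.038 at FOXA1, and no listed gene above the MET value. EGFR had 1.28 ± 0.046 in NCI-H2087 and 0.825 to 1.07 in the other lines, and TERT 1.08 to 1.17 in all 4.

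NKX2-1 peaks of NCI-H2087 with more partners had more acetylation. Of the 24278 peaks with none of FOXA1, FOXA2, c-Jun, EP300 and SOX2, 41.4% overlapped H3K27ac and 32.0% CTCF, and their median NKX2-1 fold was 6.42. Of the 2445 peaks with all 5, 88.8% overlapped H3K27ac, 47.8% RNA polymerase II and 15.7% CTCF, with a median fold of 29.8. Peaks with 2 partners had less H3K27ac (44.8%) and less RNA polymerase II (16.8%) than peaks with 1 (52.2% and 27.6%). SOX2 and EP300 regions overlapped 8.08-fold over the number expected from their totals, 42.0% of EP300 regions holding SOX2, and FOXA1 regions held FOXA2 in 92.1% of cases.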
